A study of Sus scrofa domesticus with 4 samples.

How the data were processed

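The series holds 4 two-colour Agilent microarrays of porcine endometrium, the lining of the uterus. Per the labels' protocols, explants of about 100 mg and 3 mm thickness were cut from the uterine horns of 4 gilts on days 15 to 16 of gestation. They were kept in 2 mL of culture medium, first for 2 h alone and then for 24 h with 10 nM orexin B (a hypothalamic peptide, also called hypocretin 2) or with no treatment. RNA with an integrity number between 8 and 10 was labelled with Cy3 or Cy5, and 825 ng of each labelled cRNA was mixed for each array. Every array therefore compares treated with untreated RNA. The labels speak of 4 animals without tying an animal to an array, so the 4 arrays are the replicates here. Gene p-values rest on the spread between these arrays, moderated by a variance shared between probes. The main test of gene lists, camera with a preset correlation, takes its p from the number of genes and not from that spread.

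Each array's dye labels put the treated RNA in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4. The labelling text shared by all samples can also be read as untreated RNA in Cy3 throughout. The dye labels of each array were used, and the other reading is an alternative. In the authors' value table the columns of arrays 2 and 4 run opposite to the scanner ratio (correlation of -1 with the scanner's log2 of Cy5 over Cy3, and 1 for arrays 1 and 3), so the authors turned the same arrays. The 10 spike-in controls had Cy5 over Cy3 ratios that correlated at 0.993 or more between arrays, so they did not turn with the labelled orientation. If the spike-in RNAs were added by dye, this says nothing on which tissue RNA carried which dye. If they were added by tissue RNA, it would go against the labelled swap. That they went with the dye was assumed and not established.

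The deposited spot intensities of each channel came from Agilent Feature Extraction 10.7.3.1 on array design 026440, per the file headers. The same files give a log10 ratio of Cy5 over Cy3 after the scanner software's own background and dye correction, per the file headers. The series' value table holds log2 ratios of treated over untreated that match this log10 ratio in scale after conversion, as deposited by the authors. Its columns are not centred and have medians of 0.18, 0.29, 0.01 and 0.03 for arrays 1 to 4.

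The fit started from the median spot signal and the median local background of each channel, because the plan's mean signal is not among the columns used here. Background was corrected by normexp with an offset of 50, and each array was normalised by loess with control and outlier spots at weight 0 (limma 3.58.1 in R 4.3.3). Outlier spots were left out of the fit and the spots of each probe were averaged, which gave 43603 probes from 43803 spots. A probe was tested if it was well above background on all 4 arrays in the channel of at least 1 condition, which left 13783 probes, of which 11144 were above background in every channel. Of the tested probes, 215 lacked a value on at least 1 array because of outlier spots, and for 2 of these the arrays left had a single dye orientation, so that their ratio is not separated from the dye. No tested probe was below background on every array of a condition, and no spot was saturated. For each probe, limma's lmFit and eBayes fitted a treatment term (+1 for treated in Cy5, -1 for treated in Cy3) and a dye term, which left 2 residual degrees of freedom. Standard errors (±) and 95% intervals are from this fit, with the dye term taken out. Their variance is moderated, with 5.09 prior degrees of freedom shared between probes beside the 2 residual ones. They are not the scatter of the 4 arrays: PRKAR1A and PLAU both have ± 0.17, with an SD over arrays of 0.07 and 0.89. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05.

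Probes were named through the RefSeq accessions in the scanner files and the RefSeq gene table of assembly Sscrofa11.1, without versions, and no coordinates are given because the array files used here name no build. This named 6700 probes of 3029 genes, and 3637 tested probes of 1637 genes. The other 36903 probes, most with a transcript or cluster identifier, carry no gene name here. A gene is represented by its tested probe with the highest mean signal, and 770 genes had more than 1.

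Before the data were examined, 26 gene lists were fixed for pregnant endometrium, for explant culture, for orexin signalling and for markers of the cell types that an explant can hold. Lists with at least 5 tested genes (17 of them) were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. The same lists were tested by camera with an estimated correlation and by fry, limma's self-contained test. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom, so this test is also weaker for want of arrays. The rule for named genes was also fixed then. It takes the orexin genes always, the genes past the adjusted threshold, up to 2 genes per list by smallest p where a list has no such gene, and, where too few pass, 10 genes in each direction by smallest p among those with the same sign on all 4 arrays and a change of at least 1.2-fold. As no probe passed, every gene is named by its values. Members of lists printed beyond this rule were chosen after their values were seen.

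On simulated ratios for 13568 probes with the fitted spread and dye effects, the fit recovered 0% of 50 probes changed 1.5-fold, 8% of 50 changed 2-fold, 96% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 4 calls among the unchanged probes. With no change simulated it made 0 calls. The camera test found a simulated list of shifted genes among 1637 and called 0 of 20 unshifted lists. The shifted list was given about the size and median of the interferon list. Noise was drawn independently for each gene, so the simulation cannot show how camera behaves with correlated genes or structure among arrays. The number of arrays limits the precision: the median standard error of a log2 ratio was 0.19.

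Array 2 was scanned on another day than the other arrays, per the file headers. Its header names another slide, while the name of its deposited file carries the slide of the others, so its slide is uncertain. As its scan holds no other array, no block could be fitted with more than 1 array in each. A dye term of its own for array 2 is the same as leaving that array out, which is among the alternatives. Other alternatives were normexp without an offset, no background correction, the scanner's own log ratio, median centring, Aquantile scaling between arrays (which leaves the ratios as they are), other filters, no dye term, array weights, an intensity trend, the authors' value table, a test per gene, and a separate-channel fit without the pairing of the channels. The channels of an array are paired by design: their deviations from the mean of each dye correlated at 0.38 to 0.57 within an array.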

Results

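The data are 4 arrays, each with RNA of explants treated with 10 nM orexin B for 24 h in one dye and RNA of untreated explants in the other, with 2 arrays of each dye orientation. The question is how orexin B alters gene expression in the endometrium of gilts at the time of conceptus attachment. Between 82.4% and 86.7% of the 43803 spots were well above background in Cy5 on arrays 1, 3 and 4, against 46.8% on array 2, which was scanned on another day. In Cy3 the share was 27.8% to 36.2% on the 4 arrays. Positive log2 ratios mean more RNA in the treated explants.

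No single gene passed the adjusted threshold, and the genes given here are those with the smallest p-values among genes whose ratio had the same sign on 4 of 4 arrays. BCL2A1, a survival factor of the BCL2 family that NF-kappaB induces, had a log2 ratio of -1.27 ± 0.21 (moderated SE of the fit, n = 4; 95% interval -1.76 to -0.79), which is 2.42 times lower. FABP5, a fatty acid binding protein, stood at -1.39 ± 0.26, with all 4 of its probes between -1.44 and -1.39. GP91-PHOX, the catalytic subunit of the phagocyte NADPH oxidase, stood at -1.04 ± 0.22, the co-stimulatory receptor gene CD86 at -0.68 ± 0.19 and the chemokine receptor gene CCR7 at -0.81 ± 0.23. In the other direction, TFAP2C, a transcription factor of trophoblast and epithelia, stood at 1.14 ± 0.19 (2.21-fold) and FASN, the fatty acid synthase gene, at 0.67 ± 0.19. For TFAP2C the other tested probe was at 0.55, and the dye term of the probe named here was 0.64. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, stood at 0.66 ± 0.19, and OXTR, the oxytocin receptor gene, at 0.45 ± 0.17.

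The other genes named by the same rule were UBD (-0.82), CCL5 (-0.81), CXCL11 (-0.78), OASL (-0.90) and DDIT4 (-0.73) on the lower side. On the higher side they were LGALS1 (0.82), ID1 (0.70), PPIA (0.51), MET (0.49), SRPK3 (0.48) and VDAC2 (0.46). The rule admits only genes with the same sign on 4 of 4 arrays, so that sign is no result. All tested probes of each gene had the same sign, though for some not the same size. The other PPIA probe was at 0.07, and the DDIT4 probes ran from -0.84 to -0.24. Over all 13783 probes, limma called 0 higher and 0 lower, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 there were 495 probes (237 higher and 258 lower), or 3.59%, against 689 that chance alone would give. Without array 2, 15 probes passed (12 higher and 3 lower), of which MUC20, chosen after its value was seen, was at 1.69 (adjusted p = 0.0353), against 0.93 with all arrays. In a test per gene on the mean of its probes, BCL2A1 and FABP5 passed at an adjusted p = 0.0106 each, while the test on each gene's brightest probe called 0 genes. BCL2A1 has 1 tested probe, so averaging left its ratio at -1.27. Its unadjusted limma p went from 0.000444 to 1.13e-05 through the variance that the fit shares between genes, not through more data.

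**Figure D1:**
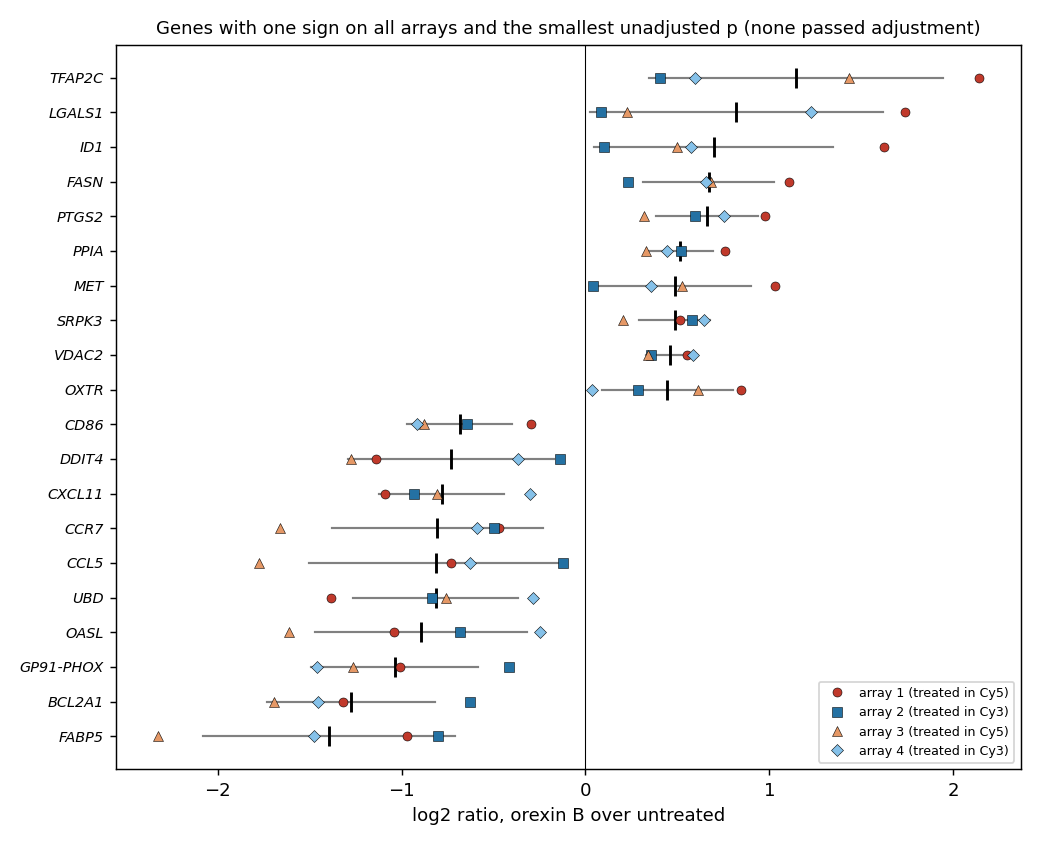
Log2 ratio of orexin B over untreated for 20 genes, the 10 in each direction with the smallest unadjusted p among those with the same sign on 4 of 4 arrays and a change of at least 1.2-fold; symbols are the 4 arrays, black ticks the fitted mean and grey lines 1 SD over arrays. All 4 arrays lie on one side of 0 for each gene by this choice, and array 2 lies nearest to 0 for several genes, such as BCL2A1 at -0.63.

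Genes induced by interferons, which the conceptus secretes around attachment in pigs, mostly had a lower ratio in treated explants. Of the 25 tested genes of this list, 23 had a lower ratio and 2 a higher one, with a median log2 ratio of -0.40, and none passed on its own over all probes. The median was below 0 on all 4 arrays, at -0.70, -0.27, -0.50 and -0.33. With median centring the median of the list was -0.03, which is -0.31 against all tested probes. Adjusted over the list alone, 3 genes passed, namely OASL (-0.90 ± 0.19), CXCL11 (-0.78 ± 0.19) and IFIT3 (-0.71 ± 0.18), each with an adjusted p = 0.0484. On array 2 IFIT3 stood at 0.19, and RSAD2, at -0.83 ± 0.23 over all arrays, stood at 0.63. ISG15 stood at -0.50 ± 0.18 and MX1 at -0.40 ± 0.19, whereas MX2 (0.02) and EIF2AK2 (0.13) stood near 0 with large spread. Camera set the list apart from the other tested genes at an adjusted p = 1.57e-09, and at an adjusted p = 0.321 with an estimated correlation. That estimate, 0.000993, was below the preset 0.01, so a higher correlation is not what lost the call. It was lost because camera with an estimated correlation takes its p from the 2 residual degrees of freedom of the arrays. With a preset correlation it takes the p from the number of genes. If all arrays are read as treated in Cy5, the call is lost as well (adjusted p = 0.506).

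**Figure D2:**
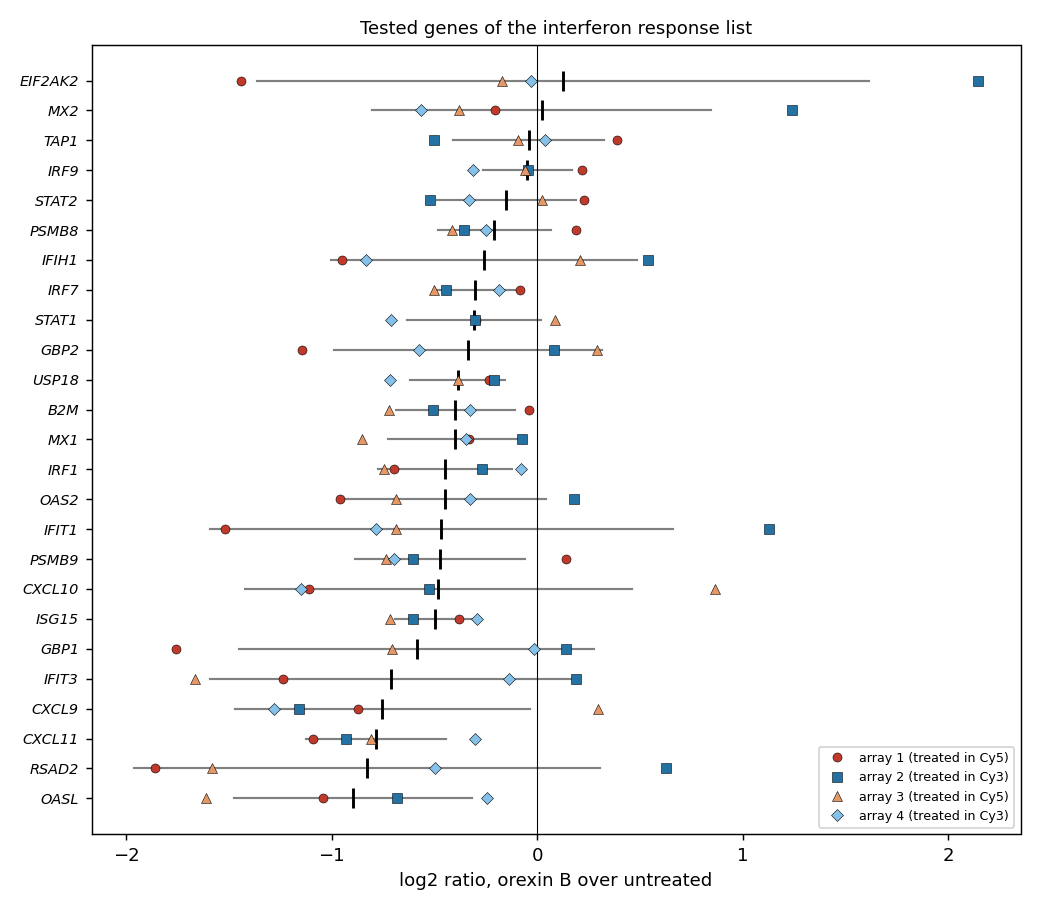
Log2 ratio of orexin B over untreated for the 25 tested genes of the interferon list; symbols are the 4 arrays, black ticks the fitted mean and grey lines 1 SD over arrays. Means lie below 0 for 23 genes, and array 2 lies above 0 for some of them, such as IFIT1 and RSAD2.

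Cytokine, chemokine and NF-kappaB genes also mostly had a lower ratio. Of 27 tested genes, 24 had a lower and 3 a higher ratio, with a median of -0.25 and array medians of -0.17, -0.23, -0.26 and -0.28. Among the lowest were CCL5 (-0.81 ± 0.23) and CXCL8 (-0.59 ± 0.17), chemokines for T cells and neutrophils, ICAM1 (-0.58 ± 0.18), TNFAIP3 (-0.54 ± 0.19) and IL1B (-0.46 ± 0.18), whereas TNF (0.02) and CCL2 (-0.02) stood near 0 and IL18 at 0.53 ± 0.28. Adjusted over the list alone, 0 genes passed. The camera adjusted p was 7.22e-05, and the adjusted p = 0.544 with an estimated correlation did not pass. With the arrays centred on their medians in place of loess, the list's median was 0.05, while that of all tested probes moved to 0.28, so the list stayed 0.23 below it (a difference of -0.23).

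Apoptosis genes mostly had a lower ratio and extracellular matrix genes a higher one, by smaller medians with loess. With median centring, matrix genes were no nearer to all tested probes than cytokine genes, and no test compared the lists with each other. Of 15 tested apoptosis genes, 12 had a lower ratio (median -0.20; with median centring 0.05, which is -0.23 against all tested probes). The array medians were -0.60, -0.14, -0.47 and 0.00, so array 4 showed no drop. Adjusted over the list alone, 1 gene passed, BCL2A1 (adjusted p = 0.00666). CASP1, which matures interleukin 1, stood at -0.50 ± 0.19 and CASP8 at -0.39 ± 0.17, so the members that stood lowest include both an inhibitor of cell death and caspases. The camera adjusted p was 0.0211, against an adjusted p = 0.544 with an estimated correlation. Without array 1 it was 0.0608 and without array 4 it was 0.215. Of 22 tested matrix genes, 18 had a higher ratio, with a median of 0.15 (0.13 against all tested probes; with median centring 0.55, which is 0.27 against them). POSTN, a matrix protein of fibroblasts, stood at 0.59 ± 0.20 with 6 of its 6 probes higher. The urokinase gene PLAU stood at 0.39 ± 0.17 beside a larger dye term of 0.77, as some named genes of other lists also had. Adjusted over the list alone, 0 genes passed. The array medians were 0.33, 0.07, 0.21 and -0.22, so array 4 went the other way. The camera adjusted p was 0.00375, against an adjusted p = 0.544 with an estimated correlation, and with the preset correlation it was 0.213 without array 2 and 0.0673 without array 3. The estimated correlation was 0.0606 for the matrix list, above the preset 0.01, and -0.0759 for the apoptosis list.

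**Figure D3:**
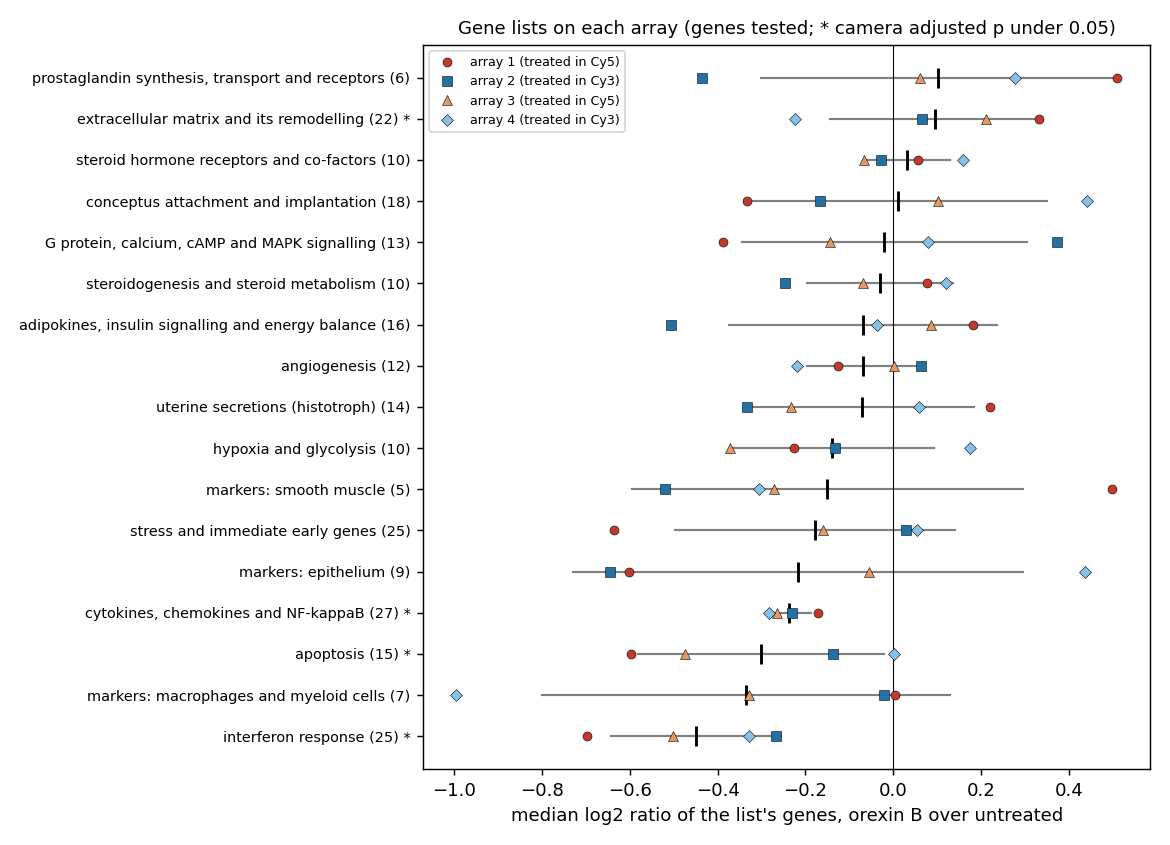
Median log2 ratio of each tested gene list on each array; symbols are the 4 arrays, black ticks the mean of the array medians, grey lines 1 SD, numbers the genes tested and stars the lists with a camera adjusted p under 0.05. The interferon and cytokine lists lie below 0 on all 4 arrays, while most other lists fall on both sides of 0.

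Lists tied to pregnancy did not stand apart from the other genes. Their medians with median centring are given as they stand, where the median of all tested probes was 0.28. The prostaglandin list had 6 tested genes with a median of 0.14 (with median centring 0.43, without array 4 -0.11 and without array 2 0.40; camera adjusted p = 0.399) and 0 genes adjusted over the list alone. Beside PTGS2, the thromboxane synthase gene TBXAS1 stood at -0.43 ± 0.20. The attachment list had 18 tested genes, 9 higher and 9 lower (median -0.05, with median centring 0.29, mean 0.11, adjusted p = 0.266, 0 adjusted over the list alone). In it the osteopontin gene SPP1, whose protein links integrins of uterus and conceptus, stood at 0.77 ± 0.36 with 4 of 4 probes higher, but at -0.56 on array 2, and leaving out an array gave 0.26 to 1.29. The galectin gene LGALS1 stood at 0.82 ± 0.30 and IHH, a progesterone target, at -0.51 ± 0.20. Without array 2 this list passed, with a median of 0.11 (camera adjusted p = 0.00537), and leaving out an array gave medians of -0.12 to 0.13. That pass used the preset correlation of 0.01, where the estimate for this list with all arrays was 0.168. Steroidogenesis genes had a median of -0.12 over 10 genes (with median centring 0.19, leaving out an array -0.17 to 0.02, adjusted p = 0.522, 0 adjusted over the list alone), with TSPO at -0.23 ± 0.20 and HSD17B8 at -0.19 ± 0.18. Steroid receptors and their co-factors had a median of 0.07 over 10 genes (with median centring 0.31, with the authors' value table -0.03, leaving out an array 0.01 to 0.14, adjusted p = 0.522, 0 adjusted over the list alone), with NR3C1 at -0.30 ± 0.17, whose 2 probes differed in sign, and NR2F2 at 0.30 ± 0.19. The 14 tested genes of uterine secretions had a median of -0.12 (with median centring 0.22, leaving out an array -0.18 to -0.03, adjusted p = 0.522, 0 adjusted over the list alone). In it LCN2 stood at -0.47 ± 0.30, and leaving out an array gave -0.88 to -0.06.

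Lists for metabolism, stress and signalling did not pass either. Here too a median with median centring stands beside 0.28 for all tested probes, so a value above 0 is not by itself a reversal. Among adipokine and insulin genes (16 tested, median -0.16, with median centring 0.10, leaving out an array -0.16 to 0.02, adjusted p = 0.664), 1 gene passed adjusted over the list alone, FABP5 (adjusted p = 0.0169). Stress and immediate early genes had a median of -0.18 over 25 genes (with median centring 0.20, adjusted p = 0.140, 0 adjusted over the list alone), with DDIT4, an inhibitor of mTOR signalling, at -0.73 ± 0.17 and MT1A at -0.48 ± 0.19. The other MT1A probe was at -0.05. Without array 3 this list passed at a median of -0.22 (adjusted p = 0.00738). Hypoxia and glycolysis genes had a median of -0.21 over 10 genes (with median centring 0.21, adjusted p = 0.207, 0 adjusted over the list alone), with PDK1 at -0.53 ± 0.22 and LDHA at -0.32 ± 0.18. Angiogenesis genes had a median of -0.11 over 12 genes (with median centring 0.22, leaving out an array -0.14 to -0.02, adjusted p = 0.522, 0 adjusted over the list alone), with VEGFA at -0.30 ± 0.18 and ANGPT2 at -0.33 ± 0.20. G protein, calcium, cAMP and MAPK genes had a median of -0.04 and a mean of 0.02 over 13 genes (median with median centring 0.35, leaving out an array -0.06 to 0.14, adjusted p = 0.522, 0 adjusted over the list alone), with RGS5 at 0.39 ± 0.19 and PRKAR1A at 0.23 ± 0.17. Only 4 cell cycle genes were tested, too few for a list test, with a median of -0.26, with median centring 0.06, and 0 adjusted over the list alone; CDKN1B stood at -0.31 ± 0.18 and BIRC5 at -0.26 ± 0.18.

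No list of cell type markers passed with loess and all 4 arrays, and marker ratios do not separate a change in cell share from one in expression. Medians with median centring are again to be read beside 0.28 for all tested probes. Macrophage and myeloid markers had a median of -0.33 over 7 genes (camera adjusted p = 0.156), with array medians of 0.00, -0.02, -0.33 and -0.995. AIF1 stood at -0.59 ± 0.26 (leaving out an array -0.94 to -0.24) and CD14 at -0.42 ± 0.20 (-0.58 to -0.26). The macrophage list passed with median centring, at a median of -0.03 (-0.31 against all tested probes, adjusted p = 0.0310), and without array 2, at a median of -0.26 (adjusted p = 0.00537). Leaving out each array in turn gave medians of -0.50 to -0.11, with a camera adjusted p of up to 0.995. The 4 tested T and NK cell markers had a median of -0.26, and with median centring -0.29 (-0.57 against all tested probes), with GZMB at -0.38 ± 0.17 and CD3G at -0.27 ± 0.18. The 4 granulocyte and mast cell markers had a median of -0.16, and with median centring 0.06 (-0.22 against all tested probes), with S100A8 at -0.73 ± 0.25 and S100A12 at 0.29 ± 0.26. Epithelial markers had a median of -0.20 over 9 genes (with median centring 0.22, adjusted p = 0.495), with array medians from -0.65 to 0.44. CLDN3 stood at -0.54 ± 0.21 (leaving out an array -0.76 to -0.32) and CLDN4 at -0.51 ± 0.22 (-0.76 to -0.25). Under other settings they reached -0.13 and -0.16. Without array 4 the epithelial list passed, at a median of -0.48 (camera adjusted p = 0.00716), and without array 2 its median was 0.15. In the fit without array 4, array 2 is the only array with treated RNA in Cy3. The passes of these marker lists used the preset correlation of 0.01. With all arrays the estimated correlation was 0.595 for epithelial and 0.29 for macrophage markers, so a preset of 0.01 makes their p-values too small. Smooth muscle markers had a median of -0.06 over 5 genes (with median centring 0.29, leaving out an array -0.22 to 0.05, adjusted p = 0.664), with DES at -0.53 ± 0.38 and CNN1 at -0.21 ± 0.19. The 3 fibroblast markers had a median of 0.20, and with median centring 0.58 (0.30 against all tested probes), with DCN at 0.23 ± 0.19 and LUM at 0.20 ± 0.24, of whose 6 probes 4 were higher. The 4 endothelial markers had a median of -0.21, and with median centring 0.09 (-0.19 against all tested probes), with CDH5 at -0.39 ± 0.17 and PECAM1 at -0.34 ± 0.27, of whose 3 probes 2 were lower. Of the 3 tested markers of trophoblast and conceptus, 1 passed adjusted over the list alone, TFAP2C (adjusted p = 0.00175), and IL1B2, the conceptus form of interleukin 1 beta, stood at -0.42 ± 0.18. In each other marker list with a tested gene, 0 genes passed adjusted over the list alone. No B cell, plasma cell or red blood cell marker was tested.

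Genes of the orexin system gave no ratio that could be tested. HCRT, which encodes the orexin precursor, was above background in the Cy5 channel of all 4 arrays and in 0 Cy3 channels, so in treated and untreated RNA alike on 2 arrays each. The receptor gene HCRTR1 was above background in 0 channels. For HCRTR2, 1 probe was above background in 0 channels and the other in 3 Cy5 channels. On arrays 1, 3 and 4, 82.4% to 86.7% of all spots were above background in Cy5. A signal above background in Cy5 alone therefore does not establish that HCRT or HCRTR2 is expressed.

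The dye term gave the technical background of these comparisons. Limma called 0 probes with a dye effect at the adjusted threshold (smallest adjusted p = 0.290), against 1950 probes, or 14.1%, at an unadjusted p under 0.05. Several named genes had a dye term larger in size than their treatment ratio, among them PLAU (0.77), CLDN3 (-0.70), VEGFA (-0.52) and S100A12 (0.95). Across the tested probes, which are not independent, Cy5 over Cy3 ratios of arrays 1 and 2 correlated at 0.38 although their dye orientations are opposite, those of arrays 3 and 4 at 0.27 and those of arrays 1 and 4 at 0.17, while the remaining pair of opposite orientation, arrays 2 and 3, was at -0.05. Arrays 1 and 3, of the same orientation, correlated at 0.35, and arrays 2 and 4 at -0.03. Only 7.30% of probes had the same treatment sign on 4 of 4 arrays, where chance alone gives 12.5%. A two-sided exact sign-flip test on 4 arrays cannot give a p below 0.125.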

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

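The tests of the patterns in this part were chosen after the results were seen, except the sign patterns of the list tests. An array was singled out where its gap to the nearest of the others took up most of the range of the 4 arrays, which chance does in about 1 of 20 groups; this held for 1 of 56 named genes (about 2.8 by chance), 1 of 23 lists (1.2) and 2 of 6 array measures (0.3), the last both on array 2. On array 2, 20481 spots were above background in Cy5, against 36078 to 37973 on the others, and the median Cy3 signal was 236, against 454 to 484.5. CCR7 stood at -1.66 on array 3, against -0.59 to -0.47 on the others. The median of the cell cycle list was 0.28 on array 1, against -0.33 to -0.24 on the others.

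The first pattern is the lower signal of interferon and cytokine genes in treated explants. A dye bias left in the ratios would turn its sign with the dye orientation, but with the arrays oriented as labelled the medians of both lists were below 0 on all 4 arrays, the highest at -0.17. With the preset correlation a single array does not carry the interferon list, whose highest camera adjusted p over the 4 fits without an array was 0.00108; with all arrays the adjusted p = 0.321 with an estimated correlation, for which no array was left out. A smaller share of leukocytes in the treated explants may account for it: the 15 tested leukocyte markers had a median of -0.26, and their array medians were 0.09, -0.30, -0.30 and -0.61 beside -0.70, -0.27, -0.50 and -0.33 for interferon genes. This stays open, as does a response of the tissue to orexin B, which was not tested separately.

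The second pattern is that Cy5 over Cy3 ratios go together in 3 of the 4 pairs of arrays of opposite dye orientation, the exception being arrays 2 and 3 at -0.05. A probe-specific dye effect shared by arrays 1, 3 and 4 is consistent with their lowest pairwise correlation of 0.17, but array 4 hybridised with the dyes the other way round would give the same, and the correlation of -0.0297 between arrays 2 and 4 is too near 0 to decide. A dye effect that array 2 shares with arrays 3 and 4 stays open too: the higher of their correlations was -0.0297 over the tested probes, but over all probes they were 0.08 and 0.04. Over the tested probes the largest correlation between opposite orientations was 0.38, for arrays 1 and 2 (0.27 over all probes). Turning array 4 leaves it as it is, so that turn alone does not account for the pattern. Over all probes the largest was 0.41, for arrays 3 and 4. The other reading of the labels, with untreated RNA in Cy3 on every array, would also make the ratios go together. Read so, in a fit that can hold no dye term, 2145 probes had an unadjusted p under 0.05. As labelled there were 495 with the dye term and 270 with the dye term left out as well. With all arrays read as treated in Cy5, a shared dye effect would count as treatment, so this reading and a dye effect were not separated. The cause stays open, and no biological explanation was tested.

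The 4 arrays allow 7 sign patterns beside the dye term, too few for a share under 0.05. At an unadjusted p under 0.05 the real pattern gave 495 probes and the highest of the others 1887, and 4 of the 7 patterns gave at least as many as the real one. The pattern with 1887 probes sets array 2 against the other arrays, which points to a structure among the arrays beside the labelled treatment. It is also the treatment coding with the label of array 4 turned, and the scan of array 2 and such a turn were not separated. With that coding the camera p of the interferon list was 0.251. The camera p of the interferon list was 9.22e-11 against 4.90e-10 for the smallest of the other patterns (1 of 7 as small). For cytokines it was 8.49e-06 against 0.000430 (1 of 7), for apoptosis 0.00497 against 0.0126 (1 of 7), and for the extracellular matrix 0.000662 against 0.000141 (2 of 7). The other patterns called between 0 and 6 lists, against 4 for the real one. Most of them are the treatment coding with 1 array turned, so a treatment effect would enter them in part. The 6 calls and the interferon p of 4.90e-10 came from such a pattern, with array 2 turned. Arrays 1 and 2 against 3 and 4, and arrays 1 and 4 against 2 and 3, are balanced against the treatment. These patterns called 0 and 3 lists, with a camera p of 0.0148 and 0.144 for interferon. A camera call with the preset correlation can thus arise from the structure of these arrays.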

How the results depend on the processing

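The tests on the mean of a gene's probes for lists, and of lists with all arrays read as treated in Cy5, were chosen after seeing the data. The count of 0 called probes held under 14 of 15 other settings, the exception being 2 genes in the test on the mean of a gene's probes, and leaving out an array gave 0 to 15, with 15 without array 2. Probes at an unadjusted p under 0.05 (495, 47.9% higher) numbered 1077 with median centring (97.8% higher), 1394 with no filter, 270 with no dye term, 2145 with all arrays read as treated in Cy5 (34.6% higher), 113 on the brightest probe of each gene (31.0% higher) and 128 on the mean of its probes (35.2% higher). Leaving out an array gave 357 to 1568 such probes, the most without array 4, of which 49.5% to 78.5% were higher. A dye effect was called for 6857 probes with median centring, 12 genes on the mean of probes and 0 to 6 probes when an array was left out. Without the replicate block, that is without the pairing of channels, 0 probes were called and 68 had an unadjusted p under 0.05, and the block changed no list call.

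The 4 list calls fell to 0 with an estimated correlation, with fry and with all arrays read as treated in Cy5, and numbered 3 to 5 when an array was left out. With an estimated correlation and with fry the medians are those of the report by construction (-0.40, -0.25, 0.15 and -0.20), with fry adjusted p-values of 0.236 for interferon and cytokines, 0.349 for matrix and 0.120 for apoptosis. Read as all in Cy5, the medians were -0.0904 for interferon, 0.24 for matrix, -0.23 for apoptosis and, reversed, 0.0915 for cytokines. Without each array in turn the median was 0.10 to 0.21 for matrix, -0.32 to -0.18 for apoptosis, -0.50 to -0.33 for interferon and -0.31 to -0.21 for cytokines, and the last 2 kept their calls. Among lists without a call, macrophage markers passed with median centring (-0.03, adjusted p = 0.0310).

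Of named genes, median centring turned the sign of ANGPT2 (0.0469), BIRC5 (0.0206), CDKN1B (0.0693), CNN1 (0.0378), HSD17B8 (0.0582), LDHA (0.21), PECAM1 (0.00939) and TSPO (0.15); it also moved the median of all tested probes to 0.28. CD3G was at 0.0885 with the scanner's log ratio and with the value table. Leaving out an array gave DES -1.12 to 0.0498, LUM -0.0342 to 0.44, PECAM1 -0.73 to 0.0503 and S100A12 -0.0643 to 0.65. The other 600 values of named genes under other settings and 219 without an array kept their sign. The cause of these shifts was not tested, except that gene-level tests hold fewer features and share the variance over other features than the test per probe. A block for the scan or slide was not run, as 1 of the scans holds a single array.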

Other observations

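The tests in this part were all chosen after the data were seen, and adjusted p-values are over the 4 added lists. All values with median centring in this part are differences from the median of all tested probes. The genes of the swine leukocyte antigen (SLA) complex, which present antigens to T cells, stood lower: 11 of 11 tested genes had a lower ratio, with a median of -0.37 (with median centring -0.39 against all tested probes) and array medians of -0.06, -0.25, -0.50 and -0.34. SLA-DRA stood at -0.53 ± 0.17, SLA-DQA1 at -0.51 ± 0.17 and SLA-5 at -0.52 ± 0.20. Camera gave an adjusted p = 5.08e-05 and the p was 0.179 with an estimated correlation, so whether they stood lower as a group stays open.

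Genes of fatty acid and sterol synthesis had a median of 0.15 over 10 tested genes, 7 of them higher (0.14 against all tested probes, with median centring 0.18), with FASN at 0.67 ± 0.19 and the farnesyl diphosphate synthase gene FDPS at 0.42 ± 0.17. The array medians were 0.51, -0.15, 0.46 and 0.07, the camera adjusted p was 0.0173 and the p was 0.131 with an estimated correlation. Ribosomal protein genes had a median of 0.0922 over 37 genes, 29 of them higher (0.0767 against all tested probes, with median centring 0.24, adjusted p = 0.00172, and p = 0.112 with an estimated correlation). Respiratory chain genes had a median of 0.10 over 24 genes, 17 of them higher (0.0846 against all tested probes, with median centring 0.22, adjusted p = 0.00639, and p = 0.445 with an estimated correlation), with array medians of 0.53, -0.22, 0.03 and 0.01. For these 3 lists the median on array 2 was below 0, and no shift of the group was established.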
